A study of Sus scrofa with 8 samples.

How the data were processed

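Total RNA of 8 luteal tissue samples, 4 from day 14 of the estrous cycle and 4 from day 14 of pregnancy, was analysed on a custom 1-colour Agilent miRNA array. Per the labels, the gilts were 6 to 8 months old, 100 ng of RNA with an integrity number above 8 was labelled with Cy3 for each sample, and every sample was hybridised individually as a biological replicate. Group and replicate number were taken from the labels.

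The deposited scanner files hold intensity values per spot on a linear scale, background-subtracted and spatially detrended by Agilent Feature Extraction, whose version was 10.7.3.1 per the file headers and 10.7 per the submitters' processing notes. The authors also deposited a table with a single value for every spot and array. Set against the scanner values over 2806 bright spots, its values proved to be on a log2 scale, centred to a median of 0 for every spot over the 8 arrays and running in the same direction, with slopes of 0.928 to 0.990 against differences of log2 intensity and r from 0.878 to 0.974; the scaling between arrays used by the authors stays unknown. For cyclic replicates 2 and 4 the deposited columns were taken as a score, being log2 values apart from 3 cells above 100, which were read as missing. The column medians were 0.0108, −0.000283, 0.000689 and −0.000205 for cyclic replicates 1 to 4 and −0.000302, 9.45e-05, −9.45e-05 and 0.0318 for pregnant replicates 1 to 4. This table served only as an alternative. Probe sequences and a genome build were not used for the array values.

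Control spots (715 per array) and spots marked as outliers by the scanner software (384 to 453 per array) were left out. The intensity was averaged over the 5 to 10 spots of a probe and divided by the 75th percentile of the array over targets detected on all arrays. The scaled signal was floored at 0.0344, the 1st percentile among detected probes (log2 −4.86), and log2 was taken. A probe counted as detected on an array when at least 0.5 of its spots were well above background. Targets had 2 to 4 probes, of which the probe with the highest mean over all 8 arrays was used. Where more than 1 probe of a tested target was detected (169 targets), the probes differed in the sign of the change in 12, none of them among those that passed. Porcine and other-species entries of the array were kept as separate targets under the names of the array design. The 212 targets detected on at least 4 arrays, whatever their group, were tested (163 porcine, 49 of other species). The 75th percentile intensity was 189 to 316 per array, the median coefficient of variation between spots of a probe 6.46% to 7.60%, and the median of negative control spots 0.437 to 1.29. The number of arrays limits the precision, and with 4 arrays per group the p-values rest on the spread between these samples.

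Group differences were computed as pregnant minus cyclic on the log2 scale with limma 3.58.1 (lmFit and eBayes with trend, 2-sided) in R 4.3.3 with data.table (1.17.8), and p-values were adjusted by Benjamini-Hochberg over the tested targets at a threshold of 0.05. The labels state no test. For 24 miRNA lists, limma's camera with a preset correlation of 0.01 was run on the 16 lists with at least 3 tested members, taking 1 target per miRNA name (211 names). Names were compared after the species prefix alone was dropped. Entries of 1 miRNA with and without an arm suffix, such as hsa-miR-181a-5p and ssc-miR-181a, therefore counted as separate members. This also held for miR-125a, miR-155 and miR-20b, so members and counts of these lists are not all different miRNAs. Numbers detected per array and similarity between arrays were tested by exact permutation. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Named targets were, by rule, those that passed (up to 15 in each direction), the 10 names with the highest mean signal, and of each list every member that passed and up to 4 members with the highest mean signal. Any other target named is said to have been chosen after its values were seen.

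The test, the lists, the rule for named targets and the main set of alternatives were chosen before the data were examined. These alternatives were normexp background correction (offset 50), quantile normalization, the 75th percentile over all probes, no scaling, the authors' table, the scanner's total gene signal, other detection filters, floors and probe summaries, porcine targets alone, 1 target per name, slide as a fixed or random block, the slide that held both groups, a replicate block, other variance models, each array left out, and for the lists an estimated correlation and fry. Normexp was run on the median spot signal and the median background signal, since a column of mean spot signals was not used here. Scan day as a block or restriction, slide as a block without cyclic replicate 1, and leaving out arrays for detection and similarity were chosen after seeing the data. On simulated data with the mean and residual spread of each target (212 targets, 40 changed, 50 simulations of 4 against 4) the fit recovered 93.9% of targets changed by 1 and 99.7% of those changed by 2 on the log2 scale, with 3.71% false calls among those called, and 3 of 50 simulations without any change gave a call. A raised list was recovered in 50 of 50 simulations. The noise was drawn independently for every target, with the same spread in both groups. These rates therefore do not cover correlated list members, an array that departs from its group, or the unequal spread of the real groups. The median SD over tested targets was 0.286 on the cyclic arrays and 0.171 on the pregnant ones. For neighbouring miRNA genes, names and order along the chromosome were taken from a RefSeq gene table of the pig assembly Sscrofa11.1, in which 140 of the 163 tested porcine targets were matched.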

Results

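MicroRNA (miRNA) levels were measured with 1-colour Agilent arrays in the porcine corpus luteum, the progesterone-secreting gland that forms in the ovary from the ovulated follicle. Luteal tissue of crossbred gilts was compared between day 14 of the estrous cycle (cyclic, 4 arrays) and day 14 after insemination (pregnant, 4 arrays), with 1 sample on each array. The labels call the samples individual biological replicates. Every array carried 13720 spots in 1683 probes for 686 miRNA targets, of which 407 bore porcine names, 222 human, 49 mouse and 8 cattle names. Between 22.8% and 28.8% of these spots were well above background on an array, and 0 were saturated. The target bta-miR-1260b gave 72.4% to 80.4% of the summed target signal on each array. Of the 686 targets, 166 were detected on all 8 arrays and 445 on none, and the 212 detected on at least 4 arrays were tested. Pregnant replicates 1 and 2 lay on slide 1, cyclic replicates 1 and 2 on slide 2, and replicates 3 and 4 of both groups on slide 3. Slide 1 was scanned on 1 day and slides 2 and 3 on another.

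The first comparison asked which miRNAs differed between the glands kept in early pregnancy and those of the late cycle, which are close to regression. The largest rise belonged to miR-503, an X-linked miRNA of the miR-15 seed group that targets cell cycle genes, which was 2.62-fold higher in pregnancy (log2 difference 1.39 ± 0.32, SE, n = 4 per group, adjusted p = 0.0225). Among the targets that passed, the steepest fall was that of the 3p strand of miR-21, measured with the mouse sequence mmu-miR-21a-3p, which lay at 0.220 of its cyclic level (−2.18 ± 0.41, adjusted p = 0.0105). The LH-inducible ssc-miR-132 fell to 0.392 of its cyclic level (−1.35 ± 0.38, adjusted p = 0.0443), and miR-155-5p, an miRNA of activated lymphocytes and macrophages, fell to 0.515 (−0.96 ± 0.25, adjusted p = 0.0323). These calls were not equally firm. Of 32 other settings, miR-132 passed in 13, miR-155-5p in 15 and miR-503 in 19, and mmu-miR-21a-3p passed in 27 of 31. Among the fits that left out 1 array, miR-132 and miR-155-5p each passed in 1, miR-503 in 4 and mmu-miR-21a-3p in 8. In all, 24 of the 212 tested targets passed the limma test after Benjamini-Hochberg adjustment, 11 of them higher and 13 lower in pregnancy, while 73 had an unadjusted p under 0.05. All 4 pregnant arrays lay apart from all 4 cyclic ones in 36 targets (17.0% of those tested, where chance gives 2.86%), among them 20 of the 24.

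Beside miR-503, the higher targets included its genomic companions miR-424-3p (2.04-fold, log2 1.03 ± 0.21, adjusted p = 0.0141), miR-542-5p (1.03 ± 0.20, adjusted p = 0.0111), miR-450c-5p (0.82 ± 0.21) and miR-542-3p (0.73 ± 0.21). On the cyclic arrays miR-424-3p was well above background on 1 array and at the floor on the other 3, so its fold is a lower bound and its SE is limited by the floor, and miR-2320-5p (0.89 ± 0.16, adjusted p = 0.0105) was likewise detected on 1 cyclic array and all 4 pregnant ones. The remaining higher targets were hsa-miR-129-1-3p (0.96 ± 0.25), miR-423-5p (0.76 ± 0.19), hsa-let-7b-5p (0.74 ± 0.20), miR-532-3p (0.70 ± 0.18) and hsa-miR-181a-5p (0.55 ± 0.14), with adjusted p from 0.0299 to 0.0332. The porcine target ssc-miR-181a, a separate entry of the array design, differed by 0.37 ± 0.16 and did not pass (adjusted p = 0.135). A porcine entry close in name to hsa-miR-129-1-3p, ssc-miR-129a-3p, named after its value was seen, went the other way. It differed by −0.48 and did not pass (adjusted p = 0.704). The call of hsa-miR-129-1-3p held in 11 of 30 other settings, and in 1 of the fits that left out 1 array.

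Among the lower targets, the smallest adjusted p (0.00163) was shared by miR-371-5p, whose human counterpart lies in a cluster expressed in embryonic stem cells (−1.42 ± 0.20), and miR-345-3p (−1.31 ± 0.17). A human-named target, hsa-miR-125a-3p, fell by 1.16 on the log2 scale (SE 0.33, adjusted p = 0.0462). Its call was less firm: it passed in 9 of 31 other settings, miR-345-3p in 30 of 32 and miR-371-5p in 29 of 31. Among the fits that left out 1 array, hsa-miR-125a-3p passed in 1, and miR-345-3p and miR-371-5p in 8 each. Of the 13 lower targets, 7 were porcine miRNAs with numbers above 2000. They were led by miR-9840-3p (−1.37 ± 0.25, adjusted p = 0.0105) and miR-4338 (−1.07 ± 0.27, adjusted p = 0.0300), followed by miR-9852-3p (−0.81 ± 0.21), miR-9788-3p (−0.72 ± 0.18), miR-4334-5p (−0.68 ± 0.13), miR-9850-5p (−0.68 ± 0.15) and miR-9853-5p (−0.61 ± 0.16).

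The brightest targets changed little. Of the 10 names with the highest mean signal, hsa-let-7b-5p alone passed the test. ssc-miR-21, an abundant miRNA of many tissues that restrains apoptosis, averaged 5.70 ± 0.32 in the cycle and 5.33 ± 0.13 in pregnancy (log2, SD, n = 4). Its difference of −0.37 ± 0.17 did not pass (adjusted p = 0.141) and became 0.13 under quantile normalization. For ssc-let-7a (0.27) and ssc-miR-126-3p (0.16), an endothelial miRNA, the differences were smaller, as they were for ssc-miR-23b (0.21), ssc-miR-22-3p (0.10), ssc-let-7f (0.10), ssc-miR-26a (0.04), bta-miR-1260b (−0.08) and ssc-miR-1285 (−0.11), with adjusted p from 0.273 to 0.850.

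**Figure D1:**
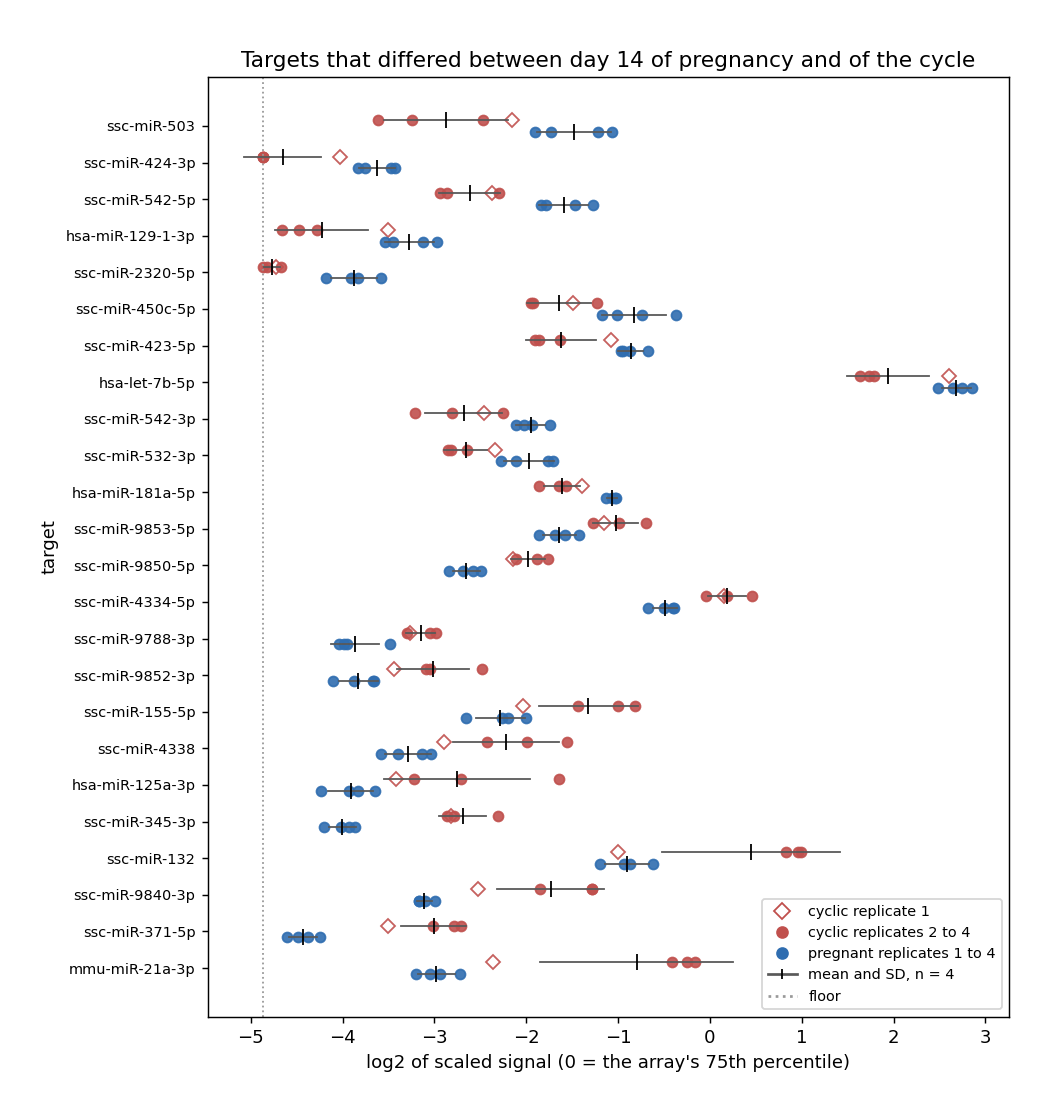
Log2 of the scaled signal (0 is the 75th percentile of the array) for the 24 targets that passed the test, with 1 point per array, cyclic arrays in red (replicate 1 as an open diamond) and pregnant arrays in blue, and the mean and SD of each group (n = 4). The log2 differences ran from −2.18 for mmu-miR-21a-3p to 1.39 for miR-503, and 20 of the 24 targets showed no overlap between the groups.

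With slide as a block, 27 targets passed (9 higher, 18 lower), 18 of them among the 24, and miR-503 and mmu-miR-21a-3p differed by 1.87 and −2.92. Slide 3 alone, with 2 arrays per group, gave 9 targets (2 higher, 7 lower), 6 of them among the 24, and every one of the 24 kept its sign there. Slides 1 and 2 each held a single group and gave no value of their own, so the differences with slide as a block are those of slide 3. These 2 settings are therefore 1 contrast, here and for the lists, and differ only in the spread used. With scan day as a block, as within the scan day that held both groups, miR-345-3p and miR-371-5p were the 2 targets that passed. All 24 kept their sign in both settings, and within that scan day miR-503 differed by 1.31 and miR-542-5p by 1.09. The count moved with single arrays as well: it was 81 without cyclic replicate 1 (41 higher, 40 lower, all 24 kept), 12 without cyclic replicate 2, 7 without cyclic replicate 3 and 9 without cyclic replicate 4. Without pregnant replicates 1, 2, 3 and 4 in turn it was 10, 10, 11 and 7. Scaling each array to the 75th percentile over all probes raised the median log2 difference of the tested targets by 0.30 and gave 62 targets (55 higher, 7 lower), and relative to that shift 26 targets passed (8 higher, 18 lower). With 22.8% to 28.8% of spots well above background on an array, this percentile lay near the limit of detection, here and for the lists.

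The second comparison asked whether miRNA groups with a shared locus, seed or cell type moved together, using 24 lists fixed beforehand, 16 of which had at least 3 tested members. The miR-15 and miR-424 family, which restrains the cell cycle, listed together with miR-450 and miR-542 from the miR-424 locus, was the 1 list that passed. Of its 11 tested members, 5 were higher (miR-503, miR-424-3p, miR-542-5p, miR-450c-5p and miR-542-3p), 0 lower, and 6 did not pass; adjusted over the list alone, 6 were higher, the sixth being miR-450a (0.73 ± 0.23), singled out after its value was seen. The mean difference was 0.54 and the median 0.73 (camera, adjusted p = 0.0109). With an estimated correlation the list gave p = 0.116 (adjusted p = 0.894). A division of the members by locus was seen only after their values, and the difference between its parts was not tested. The members with the largest differences belong to the miR-503 and miR-424 locus. Of the classical members at other loci, miR-16 (−0.05), miR-195 (−0.09) and miR-15a (−0.08) stayed near 0. There miR-15b stood at 0.30 ± 0.15 (adjusted p = 0.180) and miR-497, named after its value was seen, at 0.12. The values of miR-16, miR-195 and miR-15a became positive under the scaling over all probes, whose median shift was 0.30. The list's mean was 0.75 with slide as a block (adjusted p = 0.00130) and within slide 3, which is the same contrast (adjusted p = 0.00734). It was 0.56 with scan day as a block (adjusted p = 0.00464). It did not pass under quantile normalization (0.56, adjusted p = 0.0574), with the authors' table (0.61, adjusted p = 0.107) or with scaling over all probes (0.83, adjusted p = 0.0501), and its mean was 0.23 with normexp (adjusted p = 0.00970).

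The let-7 family, regulators of differentiation repressed by LIN28, had 9 tested members, of which hsa-let-7b-5p was higher, 0 were lower and 8 did not pass, with the same counts adjusted over the list alone. The differences were positive in 8 of the 9, including let-7c (0.54 ± 0.18, adjusted p = 0.0833) and let-7e (0.43 ± 0.16, adjusted p = 0.105), and the mean was 0.28 (adjusted p = 0.181). On cyclic replicate 1, let-7b-5p (2.61) and let-7c lay with the pregnant arrays and apart from the other cyclic arrays. The list passed with slide as a block (mean 0.46, adjusted p = 0.0161), within slide 3 (adjusted p = 0.00734), without cyclic replicate 1 (0.42, adjusted p = 0.0217), without pregnant replicate 4 (0.33, adjusted p = 0.0204) and with normexp background correction (0.25, adjusted p = 0.0123). It did not pass with an estimated correlation (adjusted p = 0.894) or with fry (adjusted p = 0.488).

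Of the miRNAs known from luteal tissue or from the response to gonadotropins, 7 were tested. miR-503 was higher and ssc-miR-132 lower, and 5 did not pass; adjusted over the list alone 2 were higher and 2 lower, miR-31 (0.35 ± 0.13) and miR-96-5p (−1.0 ± 0.32, with 3 pregnant arrays at the floor) being added. The members moved apart, with a median of 0.31, a mean of −0.04 and a camera direction upward (adjusted p = 0.839). The mean was 0.05 under quantile normalization and 0.24 with scaling over all probes. Of 8 tested leukocyte markers, miR-155-5p was lower, 0 were higher and 7 did not pass, and adjusted over the list alone 2 were lower. The added one, hsa-miR-223-3p, a neutrophil and monocyte miRNA, had the largest difference of any tested target and a wide spread (−2.29 ± 0.76, adjusted p = 0.0767). It read −0.33, −0.02 and 1.74 on cyclic replicates 2, 3 and 4, but −3.16 on cyclic replicate 1, while all 4 pregnant arrays lay between −2.84 and −2.65. Without cyclic replicate 1 its difference was −3.19. The other 6 leukocyte markers, 4 of them named after their values were seen, ran from −0.65 ± 0.45 for miR-142-5p and −0.34 ± 0.20 for bta-miR-155 through mmu-miR-342-3p (−0.10), miR-146a-5p (−0.01) and miR-150 (0.01) to hsa-miR-146b-5p (0.04), and the list's mean was −0.54 (adjusted p = 0.325). The entries bta-miR-155, which did not pass (adjusted p = 0.270), and miR-155-5p count as separate markers but bear the name of 1 miRNA.

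The fibroblast, endothelial, smooth muscle and erythroid lists gave 0 changed targets, over all targets and adjusted over each list alone. The fibroblast list (5 tested) averaged −0.35 (adjusted p = 0.337), with miR-199a-3p at −0.53 ± 0.20 and miR-214 at 0.11. It passed with slide as a block (−0.78, adjusted p = 0.0180), within slide 3 (adjusted p = 0.0345) and with normexp (−0.27, adjusted p = 0.0490), but not with an estimated correlation (adjusted p = 0.894) or fry (adjusted p = 0.488). The endothelial list (4 tested) averaged 0.08 (adjusted p = 0.741), with miR-222 at 0.16 and miR-126-5p at −0.08. For the smooth muscle and pericyte list (4 tested) the mean was −0.13 (adjusted p = 0.741), with miR-143-3p at −0.15 and miR-145-5p at 0.14, and it was 0.17 with scaling over all probes. The blood cell miRNA miR-451, from an erythroid list with 2 tested members, differed by 0.10 ± 0.62, and the other member, miR-144, by −0.13. Few epithelial miRNAs were tested: a list of the miR-200 family with the unrelated miR-203 and miR-205 had 2 tested members, hsa-miR-141-3p (0.04, detected on all 8 arrays) and hsa-miR-203a-3p (−0.46, on 4), and the miR-183 cluster 2, miR-96-5p, lower when adjusted over the list alone, and miR-182 (−0.14, on all 8). None of the miRNAs on the fixed lists for muscle and liver (miR-1, miR-133, miR-206 and miR-122), neuroendocrine cells or hypoxia reached the 4 arrays needed for testing (0 members of each list).

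**Figure D2:**
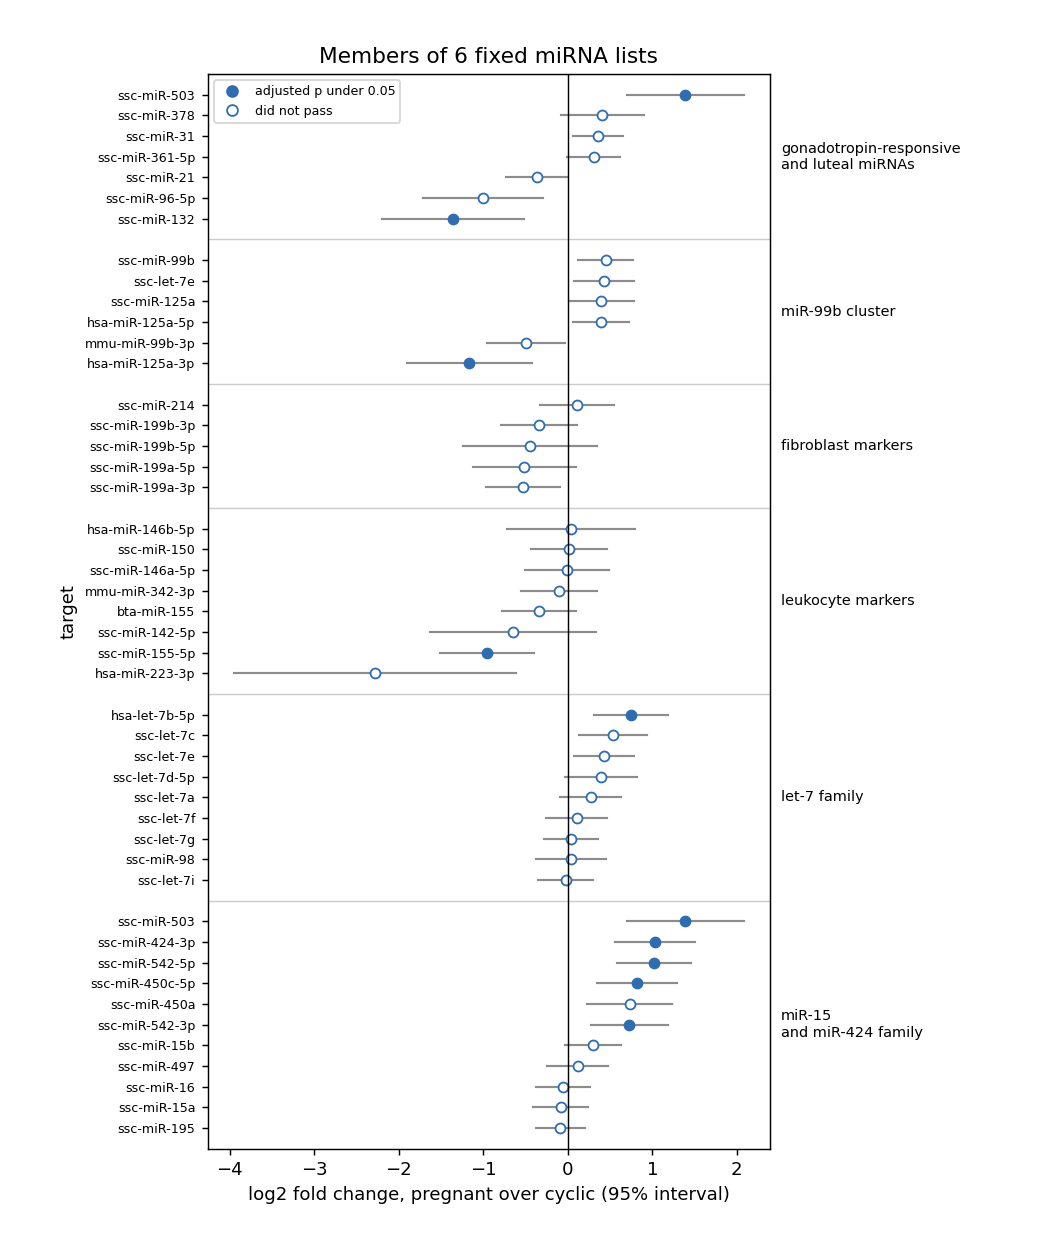
Log2 difference, pregnant minus cyclic, with its 95% interval (n = 4 per group) for every tested member of 6 of the lists, filled points marking an adjusted p under 0.05. In the miR-15 and miR-424 family, 5 of 11 members were higher, and in the let-7 family 1 of 9.

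Clustered and paralogous miRNAs made up the other lists. In the miR-99b cluster (6 tested), hsa-miR-125a-3p was lower and 5 did not pass, while adjusted over the list alone 4 were higher and 2 lower. The higher ones were let-7e, ssc-miR-99b (0.45 ± 0.15) and separate entries of miR-125a with and without the 5p suffix. The median was 0.39 and the mean 0.00, with a camera direction upward (adjusted p = 0.608), and the mean was −0.11 with slide as a block. Of the X-linked miR-532 cluster (7 tested), miR-532-3p was higher, 0 were lower and 6 did not pass, with the same counts adjusted over the list alone (mean 0.13, adjusted p = 0.608), and miR-532-5p stood at 0.38 ± 0.15. The miR-17-92 and paralogous clusters, which promote proliferation, had 13 tested members and 0 changed, 11 of them with negative values such as miR-19b (−0.30 ± 0.15) and miR-17-5p (−0.19), and their mean of −0.15 (adjusted p = 0.325) was 0.15 with scaling over all probes. In the miR-181 family (5 tested), hsa-miR-181a-5p was higher in either adjustment, 0 were lower and 4 did not pass (mean 0.11, adjusted p = 0.608).

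In 5 more lists 0 members passed in either adjustment. The 3 tested members of the miR-29 family, which represses collagen genes, were all negative (miR-29b −0.54 ± 0.20, miR-29a −0.31 ± 0.14), with a mean of −0.38 (adjusted p = 0.279), and this list passed with normexp (−0.35, adjusted p = 0.0396), as did the leukocyte list (−0.33, adjusted p = 0.0396), but neither did with an estimated correlation (adjusted p = 0.894). All 6 members of the miR-30 family were positive (mean 0.13, adjusted p = 0.424), up to 0.31 for miR-30d. The 6 tested members of the imprinted DLK1-DIO3 cluster had a median of −0.11, a mean of 0.01 and a camera direction upward (adjusted p = 0.885), with miR-127 at 0.49 ± 0.21 and miR-370 at −0.25. For miR-23, miR-27 and miR-24 (5 tested) the median was 0.02, the mean −0.06 and the camera direction downward (adjusted p = 0.885), with miR-27a at −0.49 ± 0.21, and the mean was 0.24 with scaling over all probes. The miR-100 and miR-125b clusters (4 tested) held let-7c at 0.54 and miR-100 at −0.37 ± 0.17, and their mean of −0.01 (adjusted p = 0.885) was 0.04 under quantile normalization, 0.02 with normexp and 0.29 with scaling over all probes. In each of the 2 remaining lists 1 member was tested, miR-34a of the miR-34 and miR-449 family (0.08 ± 0.13) and miR-10b of the miR-10 and miR-196 family (0.09 ± 0.11). With an estimated correlation or with the directional test of fry, 0 of the 16 lists passed. The mixed test of fry, which counts changes in either direction, passed for the gonadotropin-responsive and luteal list (adjusted p = 0.0252). It also passed for the miR-15 and miR-424 family (adjusted p = 0.0252), the miR-99b cluster (adjusted p = 0.0267) and the miR-181 family (adjusted p = 0.0478).

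The number of miRNA targets detected on each array was compared between the groups. It is not a plain measure of how many miRNAs a gland contained. Pregnant replicate 4, with the lowest 75th percentile intensity (189), detected the fewest targets (181). Cyclic replicate 4, with the highest (316), detected the most (223). How far the count follows brightness was not tested. The cyclic arrays detected 209 ± 10.5 targets and the pregnant arrays 205 ± 16.9 (SD, n = 4), a difference of −3.75 that was smaller than the spread (exact permutation test, 2-sided, p = 0.743). Within slide 3 the difference was −16.5 (exact p = 0.667, n = 2 per group). It was positive when every spot of a probe had to exceed background (2.50), without cyclic replicate 4 (0.917) and without pregnant replicate 4 (4.33).

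A further comparison asked which miRNAs were present in 1 group alone. Detection on all 4 arrays of a group and on none of the other was met by 0 of the 686 targets. The nearest cases, named here after their values were seen, were miR-424-5p and miR-708-5p (3 pregnant arrays, 0 cyclic), miR-212, the partner of miR-132 in its transcript, hsa-miR-328-5p, hsa-miR-601, miR-4332, miR-9791-3p and miR-9824-5p (0 pregnant, 3 cyclic), and miR-424-3p, miR-2320-5p, miR-2366 and miR-150 (4 pregnant, 1 cyclic), with miR-96-5p the reverse (1 pregnant, 4 cyclic). When every spot had to exceed background, miR-424-3p and miR-2320-5p met the criterion for pregnancy. Without cyclic replicate 1 it was met by 7 targets, miR-424-3p and miR-2366 in pregnancy and miR-212, miR-4332, miR-9791-3p, miR-9824-5p and hsa-miR-328-5p in the cycle. Leaving out cyclic replicate 4 gave 2 targets, as did leaving out pregnant replicate 1, and leaving out cyclic replicate 3 or pregnant replicate 4 gave 1 each.

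The last comparison asked how far reproductive status ordered the whole miRNA profiles. Over the 212 tested targets, arrays of the same group correlated at a mean r of 0.979 and arrays of different groups at 0.962, and the difference of 0.0172 was the highest of the 35 ways to split the arrays into 4 and 4 (exact permutation test, 1-sided, p = 0.0286, the smallest these splits can give). These correlations ran across targets, which are not independent replicates. Mean r was 0.987 among the pregnant arrays and 0.971 among the cyclic ones, where cyclic replicates 2 to 4 correlated at 0.981 to 0.983 with each other, and the pregnant pairs ran from 0.980 to 0.991; this difference was not tested. Cyclic replicate 1 correlated at a mean r of 0.984 with the pregnant arrays and 0.960 with the other cyclic arrays. Splits into 4 and 4 cannot set it with all 4 pregnant arrays, so the real labels were not compared with that grouping. Among arrays on the same slide, mean r was 0.980 within groups and 0.947 between them, and among arrays on different slides 0.978 and 0.967. The p was 0.0571 when any 1 pregnant array was left out, where the splits could set cyclic replicate 1 with all remaining pregnant arrays. The difference was 0.0309 without cyclic replicate 1.

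**Figure D3:**
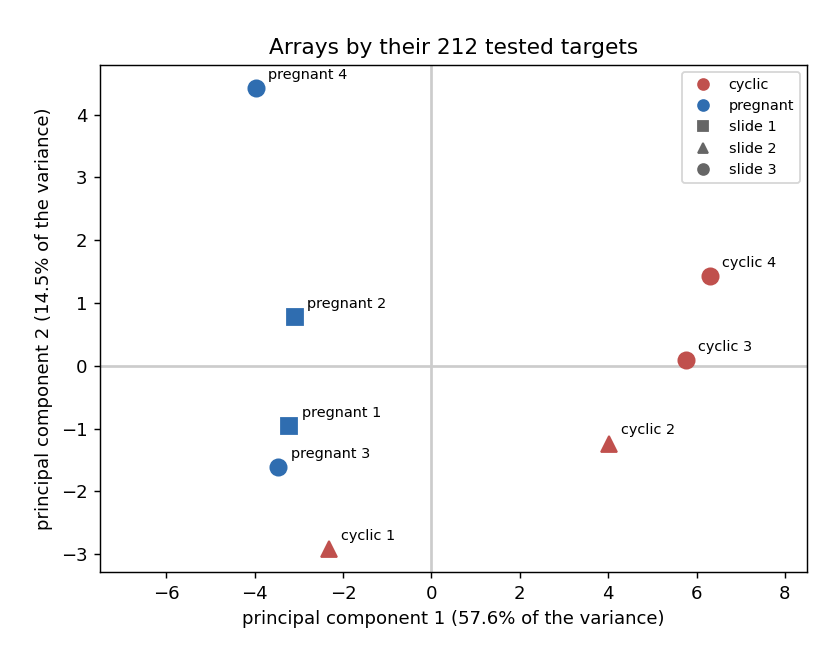
The 8 arrays on the first pair of principal components of the 212 tested targets, coloured by group and shaped by slide. Component 1 (57.6% of the variance) placed the pregnant arrays between −3.98 and −3.09 and cyclic replicates 2 to 4 between 4.02 and 6.30, with cyclic replicate 1 at −2.32 beside the pregnant arrays.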

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

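The counts over other splits of the arrays were planned, and the other tests in this part, on cyclic replicate 1, were chosen only after its position had been seen.

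Single arrays stood far from the other 3 of their group in 13 of the 190 target and group combinations examined (6.84%, where chance gives 5%), and 7 of the 13 were cyclic replicate 1. Relative to the mean of the other cyclic arrays, cyclic replicate 1 had more miR-424-3p (0.83, the other 3 at the floor), hsa-let-7b-5p (0.89), let-7c (0.77), miR-182 (0.89) and miR-31 (0.44) and less mmu-miR-21a-3p (−2.08) and miR-132 (−1.93), all on the log2 scale. In cyclic replicate 3, miR-345-3p was higher than in the other cyclic arrays by 0.52. Among the pregnant arrays, miR-96-5p (1.32) and miR-144 (0.12) were higher in replicate 1, where the other 3 were at the floor, miR-9788-3p was higher in replicate 2 (0.51), miR-127 lower in replicate 3 (−0.35) and miR-181d-5p lower in replicate 4 (−0.24).

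The profile of cyclic replicate 1 resembled those of the pregnant arrays, its values lying nearer the pregnant mean for 64 (79.0%) of the 81 targets that passed without it. Its correlation with its slide mate, cyclic replicate 2, was 0.969, below its lowest with a pregnant array (0.973), which decides nothing about the shared slide, since that slide held no pregnant array. Labels of 2 arrays swapped between the groups are argued against, as 0 pregnant arrays were nearer the other 3 cyclic arrays. A single wrong label cannot be told apart from a true cyclic gland with a pregnancy-like profile: over those 81 targets, which were selected on the 7 arrays it is compared with, its median position was 0.196 on a scale from the pregnant mean (0) to the mean of the other cyclic arrays (1), above the pregnant arrays (−0.149 to 0.0971) and far below the other cyclic arrays (0.871 to 1.15). A candidate biological explanation, that luteal regression may have begun later in this animal than in the other cyclic gilts, was not tested.

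Of the 35 ways to split the 8 arrays into 4 and 4, 1 split, the real one with 24 targets, gave as many changed targets. The highest of the others gave 1. A share of 1 in 35 (0.0286) is the smallest these splits can give, so chance is argued against for that count but not excluded. The other splits mix the groups, so a group difference widens their spread and lowers their counts. They also exchange arrays without regard to slide or scan day. For the lists, 31 of the 35 splits gave at least as many lists as the real split (1 list), the highest of the others 8, so chance cannot be excluded for the number of lists. The split with 8 lists set cyclic replicates 1 and 2 and pregnant replicates 2 and 4 against the rest and gave 0 changed targets. The split along slide 3 gave 3 lists and 0 targets, and with slide as a block the miR-15 and miR-424 family had a mean of 0.75.

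In spots outside the main measurement, 5 control probes were brighter on slide 1, which held pregnant arrays alone, than on the other slides: dmr_285 by 2.26 times, dmr_3 by 2.46, dmr_31a by 2.15, dmr_6 by 2.66 and SCorner3 by 2.43 (ratios of mean intensity). The controls hur_1 and hur_2 did not share this, at 1.06 and 0.943. Off slide 1, cyclic replicate 1 stood above the range of the other arrays for 3 of the 5 by a wide margin, with intensities of 22942 for dmr_3 (10902 to 14969 on the other arrays off slide 1), 21627 for dmr_6 (8499 to 14016) and 24487 for SCorner3 (12211 to 17737), while it was slightly above that range for dmr_31a (687, others 599 to 675) and within it for dmr_285 (1133, others 904 to 1155). On cyclic replicate 3, 1 of the 434 negative control spots read 51287 in intensity, where the next highest read 16.9.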

How the results depend on the processing

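Scan day, slide as a block without cyclic replicate 1, scaling over all probes for the lists, and arrays left out for detection, detection in 1 group and similarity were chosen after seeing the data. All 24 changed targets kept their sign in every one of the 32 settings that tested them, and 0 passed in all of these. Against 24, the count was 15 with quantile normalization, 11 with normexp, 10 with the scanner's total gene signal, 9 without scaling (3 higher and 6 lower), 9 with the floor doubled and 62 with the 75th percentile over all probes (55 higher and 7 lower against 11 and 13; median log2 difference 0.30, and 26 relative to that median). It was 11 for targets detected on at least 1 array and 1 with no detection filter. It was 9 within the slide that held both groups and 2 with scan day as a block or restricted to 1 scan day. Array weights gave 76, slide as a block without cyclic replicate 1 gave 47, and leaving out each array gave 7 to 81. The count stayed within 1.5 times under the other settings, from 17 with the authors' table to 27 with slide as a block. The replicate block gave 26, 22 of them among the 24, and the list that passed still passed (adjusted p = 0.00907). The replicate numbers do not pair the samples: same-numbered arrays deviated with r = 0.10, 0.098, −0.18 and 0.16, and only numbers 1 and 4 correlated best with their own number. Lists passing numbered 0 with an estimated correlation, the directional test of fry, quantile normalization, the authors' table or scaling over all probes, 3 with slide as a block or within slide 3, 5 with normexp, and 1 to 2 with each array left out. The mean of the miR-15 and miR-424 family, 0.54, did not pass with an estimated correlation (0.54, adjusted p = 0.894), fry (0.54, adjusted p = 0.198), quantile normalization (0.56), the authors' table (0.61) or scaling over all probes (0.83), in a range of adjusted p from 0.00130 to 0.894. The detection difference was 2.50 when all spots had to exceed background and −8.67 to 4.33 with arrays left out. Targets in 1 group alone numbered 2 with all spots and 0 to 7 with arrays left out. The similarity difference ran from 0.0128 to 0.0309 with arrays left out, and it no longer passed when any of the 4 pregnant arrays was left out (exact permutation p = 0.0571). For 93 named targets, 2439 of 2947 values stayed on the same side with the same sign, 309 no longer passed, 80 newly passed and 0 reversed; 119 changed sign with no call on either side. For all of these changes the cause was not tested. Signal over background limited what could be tested, with 445 of the 686 targets detected on no array.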

Other observations

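All tests in this part were chosen after the changes of single targets had been seen, on targets named after their values were known.

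The strands of 1 hairpin did not always move together. Of 21 hairpins with both arms tested, the difference between the 5p and the 3p arm changed between the groups in 5 (limma, Benjamini-Hochberg over the hairpins), and in 3 of these, miR-21, miR-125a and miR-140, both arms were detected on all 8 arrays. The change was 1.82 ± 0.40 for miR-21 (adjusted p = 0.0179), whose 3p arm fell while miR-21 itself stood at −0.37, 1.55 ± 0.40 for miR-125a (adjusted p = 0.0209) and −0.51 ± 0.12 for miR-140 (adjusted p = 0.0201). All 3 passed with slide as a block (adjusted p from 0.00777 to 0.0463), and the 3p arms of miR-21 and miR-125a were read with mouse and human sequences. For miR-345 (1.38 ± 0.14, adjusted p = 1.35e-04) and miR-202 (−1.02 ± 0.32, adjusted p = 0.0487) the 5p arm was detected on 5 arrays and lay near the floor, where it could show little change, so these are left aside. If both arms follow the precursor, their difference stays the same, so in the 3 hairpins strand choice or strand turnover may differ between the states, which was not tested.

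Genes that lie side by side differed less in their change than values shuffled over all placed hairpins. Among 121 hairpins placed on the pig assembly Sscrofa11.1, 23 neighbouring pairs lay within 10000 bases, and the members of a pair differed in log2 fold change by 0.255 on average, against 0.487 for shuffled pairs (permutation test, 10000 shuffles, p = 2.00e-04), with 16 of the 23 pairs of the same sign. On the X chromosome miR-450a (0.73), miR-450c-5p (0.82) and miR-542 (mean of both arms 0.88) were close, as were miR-18a (−0.31), miR-19a (−0.34) and miR-20a (−0.34) on chromosome 11 and miR-125a (0.39), let-7e (0.43) and miR-99b (0.45) on chromosome 6. The other 7 pairs had opposite signs. Over all 23 pairs, of either sign, the widest gaps were those of miR-96-5p (−1.0) beside miR-182 (−0.14) on chromosome 18, let-7c (0.54) beside miR-99a (−0.17) on chromosome 13, miR-532 (mean of both arms 0.54) beside miR-500 (−0.15) on the X chromosome and let-7a (0.27) beside miR-100 (−0.37) on chromosome 9. Transcription of neighbours from shared precursors would bring such closeness, but the test cannot decide it. The shuffles drew on all 121 hairpins, so a smaller gap would also arise if clustered miRNAs changed less than the others. Some pairs also shared a member, such as those that hold miR-19a.

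In the miR-503, miR-424, miR-450 and miR-542 group, singled out of its list after the values were seen, all 6 tested members were positive and 5 passed (miR-450a did not, adjusted p = 0.0619), with a mean log2 difference of 0.96 (SD 0.25 over members). The containing list did not pass with an estimated correlation (adjusted p = 0.894). A slide effect is argued against by slide 3, which held both groups. There the mean was 1.31 (SD 0.29) and 6 of 6 members kept the groups apart. The members were, however, singled out on all 8 arrays, those of slide 3 included, so this check is not independent of their choice. Signal near the background is argued against only for the 5 of 6 members (83.3%) detected on all 8 arrays, whose mean was 0.94. The filter favoured that share, since testing required detection on at least 4 arrays. From the same locus, miR-424-5p (3 pregnant arrays, 0 cyclic) was left untested, as were miR-450b-3p, miR-450b-5p and miR-450c-3p (detected on no array). Within the scan day of slides 2 and 3 the mean of the 6 members was 0.98, and without cyclic replicate 1 it was 1.08. The labels give no labelling day, so that explanation stays open, as do a higher output of this locus in pregnancy and a different share of the cells that may express it, neither of which was tested.

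Porcine miRNAs with numbers above 2000, a bound set after the values were seen, made up 53.8% of the lower targets and 8.49% of those tested: of 18 such targets 10 were negative, 7 were lower and 1, miR-2320-5p, higher, while 6 of the other 194 were lower. Fisher's exact test (2-sided, p = 1.18e-05, odds ratio 19.2) was run on a set drawn from the pattern itself and so decides nothing about it. Targets detected on no array differed by −0.0300% of the members' median drop of 0.124 in scaled signal, but they lay at background by selection and decide nothing. The median of the negative control spots, which no detection call selected, reached at most 3.12% of that drop on a cyclic array. The intensities were background-subtracted, however, which brings such spots near 0 on every array. This value therefore decides nothing about signal added to every spot of the cyclic arrays. Added non-specific signal that depends on the probe, such as binding of fragments of longer RNA that may be commoner in cyclic glands, stays open, since probe sequences were not used here.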
